A study of Sus scrofa with 189 samples.

How the data were processed

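Polyadenylated RNA of the longissimus dorsi, the long muscle beside the spine, was sequenced in 189 pigs of a first-generation cross between Duroc boars and Luchuan sows. Luchuan is a Chinese breed. Per the labels' protocols, paired-end Illumina libraries were made from muscle taken shortly after slaughter at a common age. HISAT2 2.0.5 and StringTie 1.3.3 are named in the submitters' processing notes, with the genome build Sscrofa11.1. The annotation release, the filter on transcripts and any further normalization are not given in the sources used here.

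The deposited table holds 1 value per annotated transcript and sample. Its header names no unit. The values were taken as FPKM (fragments scaled to the length of the transcript and to the mapped fragments of the library) as StringTie gives them, an inference from the deposited column layout and from sample sums that vary little. It lists 18114 transcripts of 12651 genes. No listed transcript is at 0 in more than 9.52% of the samples, so that genes silent in many animals are not analysed here. Of the genes, 10949 carry a symbol in the table, 746 were named by their identifier from a reference table and 956 have no symbol. A symbol shared with another gene is carried by 73 genes. The table gives no read counts, so the depth of each library is unknown and no counting error could be computed. Errors below are therefore the spread between animals. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. FPKM also depend on the few most abundant genes, because a gene that takes more of a library leaves less for the others. Reads shared between near-identical genes, such as the myosin heavy chains, could be assigned to either one.

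FPKM of the listed transcripts were summed per gene. Genes with a mean of at least 0.5 FPKM over the 189 samples were tested, which left 10717. Intramuscular fat content (IMF) is the only trait in the labels and its unit is not stated there. It is recorded for 164 animals. The titles of 21 of them carry the mark re-analyzed, which is not explained. These lie at both ends of the IMF range and were treated as a separate set of libraries, with 11 at low and 10 at high IMF. The other 143 animals with IMF are called first deposited here, and 25 animals have no IMF recorded. That name is not in the labels, which give no order of deposit. Each title also holds a code, whose first 9 digits are shared by 2 or more animals in 48 cases. What the code stands for is not stated, and it is only called a title code here. The labels give 2 different numbers of sows for the cross. No label says which animals share a parent, and p-values treat animals as independent unless the title code is a term. The titles name no batch. The mark may or may not stand for one, and it was a covariate of every test over both sets.

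Slopes and differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean trend) on log2(FPKM + 1), 2-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The IMF slope used the 164 animals with the mark as a covariate. It was refitted in the first deposited libraries alone, and the difference of slopes between the sets was tested as an interaction. High was compared with low IMF within the re-analyzed libraries. The mark itself was tested at the same IMF. The 146 animals of the 48 shared title codes were tested for differences between codes with a moderated F test, and the intraclass correlation (ICC), the share of variance that lies between codes, was taken from the mean squares. Variation between animals was described by the SD of log2(FPKM + 1). Chance alone gives an unadjusted p under 0.05 in a share of about 0.05 of the 10717 genes. Of the counts of such genes given below, only that for title codes exceeds this share.

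Gene lists for 24 pathways and cell types were fixed beforehand. They were adipocyte markers, fatty acid and triglyceride synthesis, lipolysis and lipid droplet, fatty acid uptake and oxidation, slow fibre genes, fast fibre genes, glycolysis and glycogen, nuclear and mitochondrial genes of oxidative phosphorylation, collagen and fibroblast, myogenic and satellite cell, muscle protein breakdown, insulin and IGF signalling, macrophage and lymphocyte, interferon response, endothelial and pericyte, red blood cell, smooth muscle, Schwann cell and nerve, immediate early genes, heat shock and chaperone, circadian clock, cytosolic ribosomal proteins, and genes known beforehand from pork quality. Not every member could be matched by symbol in the table, and only measured members enter a list. RYR1 and IGF2 are missing from the pork quality genes, MYH1 from the fast fibre genes and CD36 from fatty acid uptake. Of the 10 red blood cell genes 3 were measured. A list score is the mean over measured members of the z-scored log2 values, in SD units. Scores were compared with IMF by Pearson's r and Spearman's rho after removing the mean difference between the sets, with 2-sided permutation tests of 100000 resamples within each set, where 1e-05 is the smallest p they can give. The p-values were adjusted over the 24 lists. Camera compared each list with the other genes, with a preset inter-gene correlation of 0.01 and with an estimated one.

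The genes named were chosen by a rule set before the data were examined, as were the tests and most alternatives. For IMF, these are up to 15 rising and 10 falling genes past the threshold with a symbol and the same sign in both sets, and up to 4 members of each list with the smallest p. For the other comparisons they are the 5 largest differences in each direction, the 10 title-code genes with the largest ICC and a mean of at least 1 FPKM, the 15 most variable genes at that level, and the 10 most abundant genes. Genes named outside this rule were chosen after their values were seen, and this is said where they appear. Of the genes the rule names, 2 are not reported here.

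On simulated data with the real means and spreads, an IMF slope of 0.1, 0.2 and 0.3 log2 units per IMF unit was recovered in 61.2%, 97.0% and 100% of the changed genes among 10717. In the first deposited libraries alone these shares were 29.9%, 74.6% and 98.5%. For high against low IMF, differences of 0.5, 1 and 2 were recovered in 35.8%, 94.0% and 98.5%. For the mark, differences of 0.2, 0.5 and 1 were recovered in 28.4%, 92.5% and 100%. Interactions of 0.2, 0.3 and 0.5 were recovered in 65.7%, 88.1% and 98.5%, and ICCs of 0.3, 0.5 and 0.7 in 55.2%, 97.0% and 100%. The simulated genes varied independently, with normal errors and no outlying library, so these shares may not hold for the real data. In the real first deposited libraries 0 genes rose with IMF.

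The alternatives were a pseudocount of 0.1, no filter or a minimum of 5 FPKM, no mark, the first 4 digits of the title code as a factor, the title code as a random block, quantile normalization, a shift by the sample median, normal scores of the IMF ranks, no extreme IMF values, the first deposited libraries alone, the 41 animals of highest against the 41 of lowest IMF, and the first principal component as a covariate. For title codes, the first 6 or 4 digits as a factor and codes of at least 3 animals were tried. Alternatives chosen after seeing the data were tests of single transcripts, leaving out the 4 libraries least like the others or library 39 alone, the first deposited libraries without library 39, and leaving out each re-analyzed library in turn. The 4 libraries have a median correlation with the others more than 3 interquartile ranges below the first quartile. A covariate of Y-linked genes was planned and not run. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for summing and plots. Genotypes are not used here, so expression quantitative trait loci and allele-specific expression, which the series title names, are not analysed here.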

Results

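The longissimus dorsi transcriptome of 189 Duroc × Luchuan pigs was described by FPKM of 12651 genes. The summed FPKM of the listed transcripts ranged from 364109 to 465105 per library (median 415170), and between 7803 and 10614 genes per library reached 1 FPKM. IMF was recorded for 164 animals and averaged 3.40 ± 1.13 (SD, n = 164), with values from 0.77 to 6.84. It was 3.34 ± 0.850 in the 143 first deposited libraries, 1.69 ± 0.433 in the 11 re-analyzed libraries of low IMF and 6.03 ± 0.636 in the 10 re-analyzed libraries of high IMF. No pair of libraries held identical values, and the highest correlation between 2 of them was 0.979. The median correlation of a library with the others lay between 0.889 and 0.957, and first deposited library 39 had the lowest one.

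Genes of the fast contractile apparatus and of glycolysis were the most abundant in this muscle. Skeletal actin ACTA1 had a mean of 27441 ± 8738 FPKM (SD, n = 189) and the glycolytic enzyme GAPDH 27009 ± 6168 FPKM. The fast myosin light chain MYLPF followed with 15309 ± 4419 FPKM, the aldolase ALDOA with 15024 ± 3495 FPKM and the fast troponin TNNT3 with 12990 ± 2375 FPKM. ENO3, TNNI2, TNNC2 and the mitochondrial genes COX1 and COX3 completed the 10 highest. The 10 most abundant genes of a library held between 20.0% and 44.8% of its summed FPKM.

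Which genes differed most between animals of the same cross was described by the SD of log2(FPKM + 1), whose median over genes was 0.37. APIP, an enzyme of methionine salvage, varied most (SD 2.56 log2 units, n = 189) and ranged from a listed 0 to 94.2 FPKM. The small heat shock protein CRYAB (SD 2.10) ranged from 2.23 to 1655 FPKM, and PDK4, which restrains pyruvate oxidation, (SD 2.01) from 0.216 to 377 FPKM. The stearoyl-CoA desaturase SCD (SD 1.44) ranged from 0.209 to 96.7 FPKM and the interferon-induced IFI6 (SD 1.51) from 3.96 to 335 FPKM. The others of the 15 most variable were TMEM238, MCL1, C10orf71, MAFA, HSD11B1L, FAM53B, DSTN, MRPL57, GADL1 and NEAT1_2, with SDs between 1.44 and 1.94. TMEM238, MRPL57, MAFA and SCD also differed between the 2 sets of libraries.

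Whether muscle gene expression follows IMF was asked over the 164 animals with a recorded value. Genes of fat cells rose with IMF. ADIPOQ, which encodes the fat cell hormone adiponectin, rose by 0.29 log2 units per IMF unit (SE 0.0581, limma adjusted p = 0.00507), from 16.8 ± 8.44 FPKM (SD, n = 41) in the 41 animals lowest in IMF to 31.0 ± 15.3 FPKM in the 41 highest. PLIN1, the coat protein of the fat cell lipid droplet, rose by 0.26 (SE 0.0534, adjusted p = 0.00595), and TUSC5, which serves glucose transport in fat cells, by 0.27 (SE 0.0549, adjusted p = 0.00507). LEP, the gene of leptin, had the smallest adjusted p (0.00358) and rose by 0.15 (SE 0.0289).

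Of the 10717 genes tested, 527 had an unadjusted p under 0.05 (limma), of which 487 had a positive slope. The number 527 is no more than the share of 0.05 that chance alone gives. Whether genes that move together or the FPKM scaling made the signs uneven was not tested. In all, 9 genes rose with IMF and 0 fell (limma). The others were CEBPA, a transcription factor of fat cell differentiation (slope 0.21, SE 0.0495, adjusted p = 0.0332), the retinol dehydrogenase SDR16C5 (0.20, SE 0.0423, adjusted p = 0.00602, from 0.652 ± 0.440 to 1.80 ± 1.40 FPKM, n = 41 each), the synuclein SNCG (0.09, SE 0.0200, adjusted p = 0.0103), the mitochondrial sideroflexin SFXN4 (0.06, SE 0.0141, adjusted p = 0.0184) and ENSSSCG00000010992, a gene without a symbol named after its value was seen (0.14, SE 0.0323, adjusted p = 0.0332). On Sscrofa11.1, ADIPOQ lies on chromosome 13 from 124633684 to 124648055, PLIN1 on chromosome 7 from 55237349 to 55251510, TUSC5 on chromosome 12 from 46621117 to 46634332, and LEP on chromosome 18 from 20106179 to 20123451. CEBPA lies on chromosome 6 from 43084646 to 43085710, SDR16C5 on chromosome 4 from 75586235 to 75599786, SNCG on chromosome 14 from 87904655 to 87922110, and SFXN4 on the same chromosome from 129047838 to 129075616. All 9 slopes were positive in both sets of libraries. These slopes are no independent evidence, because the genes were called over the 2 sets together. Within the 143 first deposited libraries alone they were 0.28 for ADIPOQ, 0.27 for TUSC5, 0.28 for PLIN1, 0.27 for CEBPA, 0.22 for SDR16C5, 0.16 for LEP, 0.10 for SNCG and 0.03 for SFXN4, and 0 genes passed there (limma; 270 at an unadjusted p under 0.05, smallest adjusted p 0.896). Without first deposited library 39, 28 genes rose over both sets, the 9 among them, and 5 rose in the first deposited libraries alone (LEP, SDR16C5, SNCG, CYP4V2 and PON3, the last 2 named after their values were seen), so that ADIPOQ, PLIN1, TUSC5 and CEBPA did not pass there. The call of SFXN4 was lost under quantile normalization (adjusted p = 0.604), under the median shift (0.657) and without the mark (0.0976). It was also lost without the 2 lowest and 2 highest IMF values (0.0821) and between the 41 animals highest and lowest in IMF (0.265). That of CEBPA was lost between these 41 animals each (0.168) and with the first 4 digits of the title code as a factor (0.0579). That of SNCG was lost under the median shift (0.112). That of ENSSSCG00000010992 was lost without the mark (0.232) and without the 2 lowest and 2 highest IMF values (0.0821).

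The adipocyte markers followed IMF as a group. The slope was positive in 12 of 12 measured members, of which 5 rose over all genes and 11 adjusted over the list alone. Their score correlated with IMF at r = 0.347 (permutation p = 1e-05, the smallest the permutations can give, adjusted p = 0.00024) and rho = 0.431 (p = 1e-05, adjusted p = 0.00024). Without the 2 animals farthest from the median IMF r was 0.349. Within the first deposited libraries r was 0.253 (p = 0.00235, adjusted p = 0.0564 over the 24 lists), and without library 39 it was 0.334 there (adjusted p = 0.00168). Camera placed the list above the other genes (adjusted p = 0.000208 with an estimated correlation).

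The score of fatty acid and triglyceride synthesis genes followed IMF too, and moved with the adipocyte score between animals (r = 0.770). Of 19 measured members 18 had a positive slope, 0 rose over all genes and 7 rose adjusted over the list alone. These included the malic enzyme ME1 (slope 0.10, SE 0.0256) and the elongase ELOVL6 (0.16, SE 0.0467). They also included the acyltransferase DGAT2 (0.26, SE 0.0803) and PNPLA3 (0.08, SE 0.0224). With the adipocyte score as a covariate, PNPLA3 kept 8.45% of its slope and ME1 kept 59.12%. When library 39 was left out of that fit, PNPLA3 kept 32.35% and ME1 kept 61.31%. The fatty acid and triglyceride synthesis score had r = 0.284 (permutation p = 0.00026, adjusted p = 0.00312), rho = 0.30 (adjusted p = 0.00144) and r = 0.276 without the 2 farthest animals. Within the first deposited libraries r was 0.172 (p = 0.0404, adjusted p = 0.485). Camera gave an adjusted p = 0.0142 with an estimated correlation.

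No other list passed. Fatty acid uptake and oxidation had r = 0.20 (adjusted p = 0.0816), with 1 member, the lipoprotein lipase LPL (slope 0.15, SE 0.0410), past the threshold adjusted over the list alone. The list of pork quality genes had r = 0.223 (adjusted p = 0.0734), with 1 member, the fatty acid carrier FABP4 (0.16, SE 0.0523), past it in the same way. RYR1 and IGF2 are not among its 12 measured members. Without library 39, LPL passed over all genes (limma adjusted p = 0.02305). Of the fibre types, slow fibre genes had r = 0.0155 and fast fibre genes r = -0.0300, with MYH4, the fastest myosin, at a slope of -0.06 (SE 0.0437). Glycolysis and glycogen had r = 0.00164, nuclear oxidative phosphorylation 0.134 and mitochondrial oxidative phosphorylation 0.103, and lipolysis and lipid droplet 0.135. Cell types other than fibres and fat cells gave r = 0.0254 for collagen and fibroblast, 0.0406 for endothelial and pericyte, -0.00622 for macrophage and lymphocyte, 0.0337 for red blood cell, -0.0678 for smooth muscle and -0.151 for Schwann cell and nerve (adjusted p = 0.207). The remaining values were 0.0983 for muscle protein breakdown, 0.0970 for circadian clock, 0.0871 for heat shock and chaperone, 0.0282 for cytosolic ribosomal proteins, -0.00252 for insulin and IGF signalling, -0.0206 for interferon response, -0.0315 for myogenic and satellite cell and -0.0552 for immediate early genes. Over these 22 lists rho lay between -0.135 and 0.192, with a smallest adjusted p of 0.120. Camera called Schwann cell and nerve lower (adjusted p = 0.0142 with an estimated correlation). That list has 4 measured genes, and within the first deposited libraries its r was -0.0387 (permutation p = 0.647). The calls of 10 other lists with the preset correlation were lost (adjusted p between 0.203 and 0.680 with an estimated correlation).

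**Figure D1:**
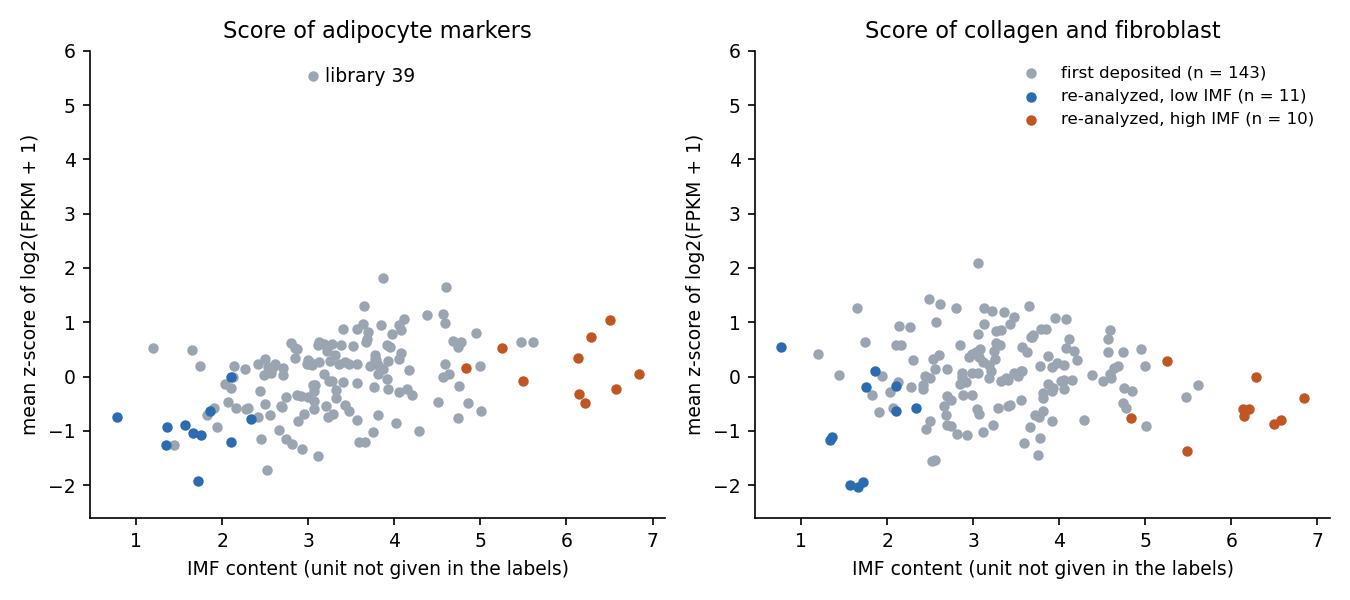
Adipocyte score (left) and collagen and fibroblast score (right), both in SD units, against the IMF content of the labels, with 1 point per animal, coloured by set of libraries. The adipocyte score rises with IMF (r = 0.347, n = 164) while the collagen score does not (r = 0.0254), and first deposited library 39 lies at an adipocyte score of 5.53.

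**Figure D2:**
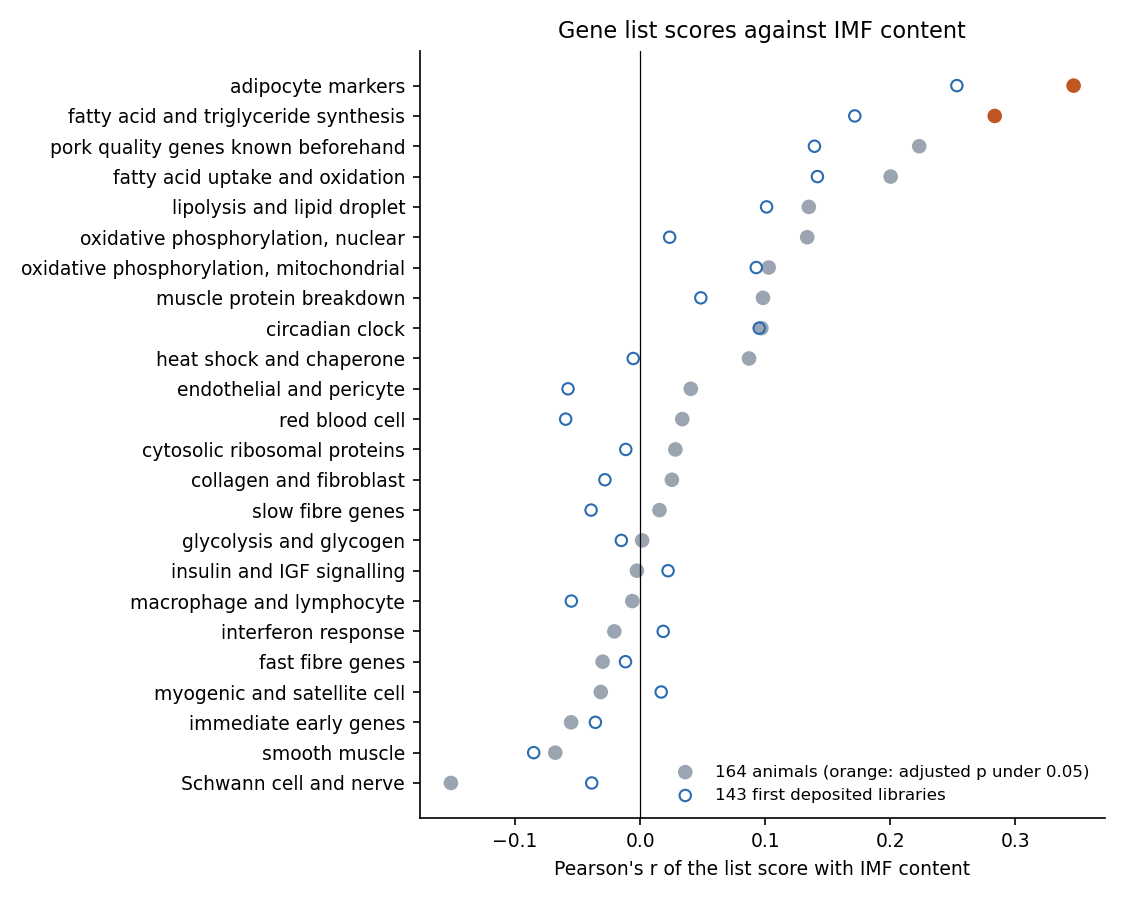
Correlation of the 24 list scores with IMF after removing the mean difference between the sets of libraries. Filled circles are the 164 animals, in orange where the adjusted p is under 0.05 (adipocyte markers and fatty acid and triglyceride synthesis), and open circles the 143 first deposited libraries alone.

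The slope of IMF was compared between the 2 sets of libraries as an interaction. The slope of ADIPOQ was 0.30 (SE 0.0569) in the re-analyzed and 0.28 (SE 0.0851) in the first deposited libraries, and that of LEP 0.15 (SE 0.0256) and 0.16 (SE 0.0427). For SFXN4 the slopes were 0.10 (SE 0.0263) and 0.03 (SE 0.0189; interaction p = 0.0227, adjusted p = 1.00). No gene passed (limma; 0 genes, 176 at an unadjusted p under 0.05).

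Within the re-analyzed libraries, the 10 animals of high IMF were compared with the 11 of low IMF, whose mean IMF differed by 4.34. Fat cell genes were higher at high IMF. ADIPOQ was higher by 1.36 log2 units (SE 0.250, limma adjusted p = 0.0311). TUSC5 was higher by 1.22 (SE 0.238, adjusted p = 0.0459), with 7.47 ± 3.48 FPKM (SD, n = 10) against 2.75 ± 2.01 FPKM (n = 11), CIDEC, which fuses lipid droplets, by 1.08 (SE 0.214, adjusted p = 0.0459), SDR16C5 by 0.91 (SE 0.172, adjusted p = 0.0372) and the adipogenin gene ADIG by 0.90 (SE 0.166, adjusted p = 0.0311), from 0.217 ± 0.169 to 1.43 ± 1.10 FPKM. CIDEC lies on chromosome 13 from 66141206 to 66149851 and ADIG on chromosome 17 from 41609468 to 41612711. Together 9 genes were higher and 0 lower (limma; 475 at an unadjusted p under 0.05). The calls of TUSC5 and CIDEC were lost with a pseudocount of 0.1 (adjusted p = 0.0611 and 0.0755) and with no filter (0.0630 for both), that of SDR16C5 with a pseudocount of 0.1 (0.0611) and that of ADIG under the median shift (0.0687).

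Of the 12 adipocyte markers, 6 were higher over all genes and 11 adjusted over the list alone, and the score rose from -0.953 ± 0.467 to 0.174 ± 0.490 (permutation p = 4e-05, adjusted p = 0.00096). The score of fatty acid and triglyceride synthesis was higher by 0.71 (adjusted p = 0.0252), with 0 members higher over all genes and 7 adjusted over the list alone. The score of the 4 measured Schwann cell and nerve genes was lower (-0.629, adjusted p = 0.0274). The number of higher genes moved with single libraries. It was 0 without low-IMF library 14 or 189, 1 without high-IMF library 31, 2 without any of 17, 20, 21, 33, 63, 136 and 160, 3 without 128 or 155, 4 without 118, 148 or 151, 5 without 34 and 17 without low-IMF library 104.

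The 21 re-analyzed libraries were also compared with the 143 first deposited ones at the same IMF, to measure how far the sets stand apart. The scores of connective tissue, vessel, immune cell and lipid synthesis genes were lower in the re-analyzed libraries, and those of ribosomal and nuclear oxidative phosphorylation genes were higher. Against the other genes, camera called 8 lists with the preset correlation, such as collagen and fibroblast (adjusted p = 5.04e-06), and none with an estimated one (smallest adjusted p = 0.545 with an estimated correlation). SCD had a difference of -1.26 log2 units (SE 0.328, limma adjusted p = 0.00114) with 3.62 ± 4.61 FPKM (SD, n = 21) against 11.4 ± 16.5 FPKM (n = 143). The fatty acid synthase FASN had a difference of -1.15 (SE 0.311, adjusted p = 0.00171), and the cofilin phosphatase SSH2 one of -1.11 (SE 0.160, adjusted p = 1.82e-08). TMEM238 was higher by 2.19 (SE 0.420, adjusted p = 1.27e-05), with 52.1 ± 28.3 against 18.8 ± 23.0 FPKM, and the mitochondrial ribosomal gene MRPL57 by 1.81 (SE 0.314, adjusted p = 1.67e-06).

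In total 1964 genes were higher and 2436 lower, of which 23 were higher and 14 lower by 1 log2 unit or more. The balance turned to more genes higher than lower under the median shift (2551 and 2145), under quantile normalization (2308 and 2267) and with a mean of at least 5 FPKM (1256 and 997). The median over all genes was -0.01. ANKRD9 (1.67), G0S2, an inhibitor of lipolysis, (46.1 ± 17.3 against 21.6 ± 23.4 FPKM) and MAFA (1.45) were the other highest, and FAXDC2 (-1.13) and the angiotensinogen gene AGT (-1.12) the other lowest. SCD lies on chromosome 14 from 111461157 to 111478031, FASN on chromosome 12 from 922418 to 937560, TMEM238 on chromosome 6 from 59554323 to 59554859 and MRPL57 on chromosome 11 from 1321085 to 1321828.

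Of the 20 collagen and fibroblast genes 17 were lower and 0 higher, among them SPARC (-0.79, SE 0.123) and COL3A1 (-0.78, SE 0.166), and the score differed by -0.799 (permutation adjusted p = 8e-05). Endothelial and pericyte genes had 6 of 11 lower and 0 higher, with the endothelial cadherin CDH5 at -0.84 (SE 0.115) and a score difference of -0.662 (adjusted p = 8e-05). Macrophage and lymphocyte genes had 8 of 11 lower and 0 higher, with the complement gene C1QB at -0.67 (SE 0.160) and a score difference of -0.666 (adjusted p = 0.000857). Adipocyte markers had 8 of 12 lower and 0 higher (score -0.547, adjusted p = 0.00664), and fatty acid and triglyceride synthesis 10 of 19 lower and 0 higher (-0.484, adjusted p = 0.000857). Red blood cell (-0.585, adjusted p = 0.0139) and smooth muscle scores (-0.414, adjusted p = 0.00454) were lower too. So were the scores of insulin and IGF signalling (-0.457, adjusted p = 8e-05), muscle protein breakdown (-0.379, adjusted p = 0.00259), myogenic and satellite cell (-0.369, adjusted p = 0.00024) and pork quality genes (-0.296, adjusted p = 0.000432). Of 23 cytosolic ribosomal genes 10 were higher, such as RPL13 (0.52, SE 0.108), and 1 was lower, RPL3 (-0.26, SE 0.0900), with a score difference of 0.510 (adjusted p = 0.00259). Nuclear oxidative phosphorylation had 15 of 28 higher, such as the cytochrome c gene CYCS (0.53, SE 0.112), and 1 lower, the citrate synthase CS (-0.32, SE 0.0686), with a score difference of 0.447 (adjusted p = 0.00456). The set and any batch of library preparation or processing cannot be told apart here.

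**Figure D3:**
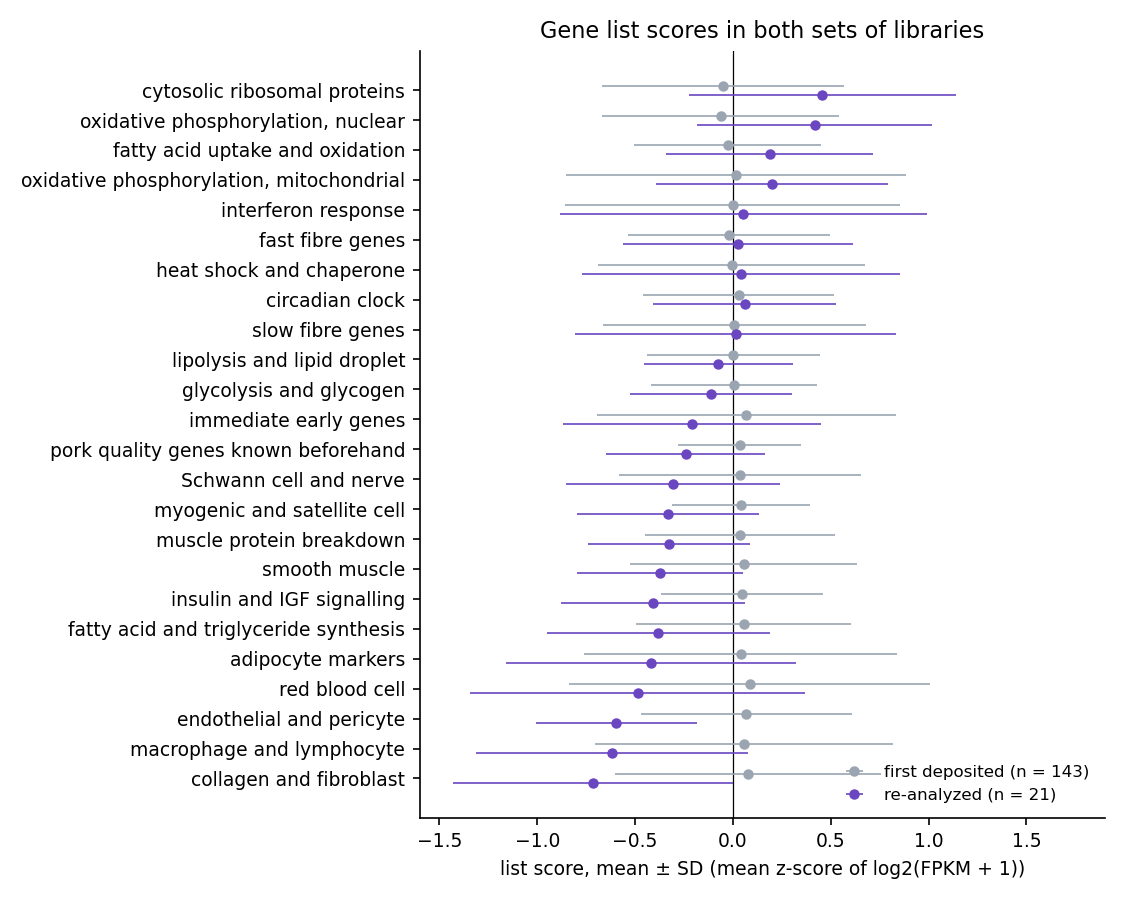
Mean list scores in SD units, with error bars of 1 SD between animals, of the first deposited libraries with IMF (n = 143) and the re-analyzed libraries (n = 21). The collagen and fibroblast, macrophage and lymphocyte, and endothelial and pericyte scores lie lower in the re-analyzed libraries (adjusted differences -0.799, -0.666 and -0.662), and the cytosolic ribosomal score lies higher (0.510).

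The series is about inherited variation of expression, and whether animals of the same title code resembled each other was tested over 146 animals of 48 codes. Genes of fatty acid and triglyceride synthesis did so most among the lists. Of 19 members 7 were called (Fisher's exact test against all tested genes, p = 2.48e-08, adjusted p = 5.96e-07). That test treats genes as independent, whereas these members were correlated between animals (mean pairwise r = 0.265), so its p overstates the evidence. They were SCD with an ICC of 0.348, ELOVL6 with 0.346, ELOVL5 with 0.325, AGPAT2 with 0.291, DGAT2 with 0.288, THRSP with 0.278 and SREBF1, a regulator of lipid synthesis, with 0.262. The list score had an ICC of 0.313 (permutation p = 0.0005, adjusted p = 0.012), and none of the other 23 lists passed (smallest adjusted p 0.0504). With the first 6 digits of the code as a factor its ICC was 0.240 and the call was lost (p = 0.0659). Over the 14 codes with at least 4 animals, the mean of SCD ranged from 1.32 to 4.84 log2 units and that of ELOVL6 from 0.85 to 2.43.

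In total 195 genes differed between codes (limma F test), 1.82% of the genes tested, and 2014 genes had an unadjusted p under 0.05. The median ICC of the 195 was 0.304 (lowest 0.260) against 0.0475 over all genes. That contrast largely follows from the call, because the ICC and the F test compare the same codes in the same animals. The count was 109 under quantile normalization and 110 under the median shift, with 85 and 82 of the 195 kept, 35 for codes with at least 3 samples and 121 without the 4 libraries least like the others. The largest ICC among named genes were those of WDR83 (0.461, adjusted p = 0.00136), a protein of splicing and signalling complexes, and of the ubiquitin ligase RNF113A (0.455, adjusted p = 0.000243), which ranged from 5.15 to 50.5 FPKM. WDR83 lies on chromosome 2 from 66303002 to 66312586 and RNF113A on chromosome X from 98218740 to 98219773. LAMB3 (0.436), RFNG (0.432), FUOM (0.418), ISOC2 (0.409), MTHFD1 (0.408), TRPT1 (0.395) and COQ4 (0.391) followed. Only 45 genes were called when codes were compared within the same first 6 digits, and the calls of LAMB3, FUOM and TRPT1 were then lost (ICC 0.315, 0.0953 and 0.194). The call of WDR83 was lost under quantile normalization (ICC 0.198) and under the median shift (0.216).

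**Figure D4:**
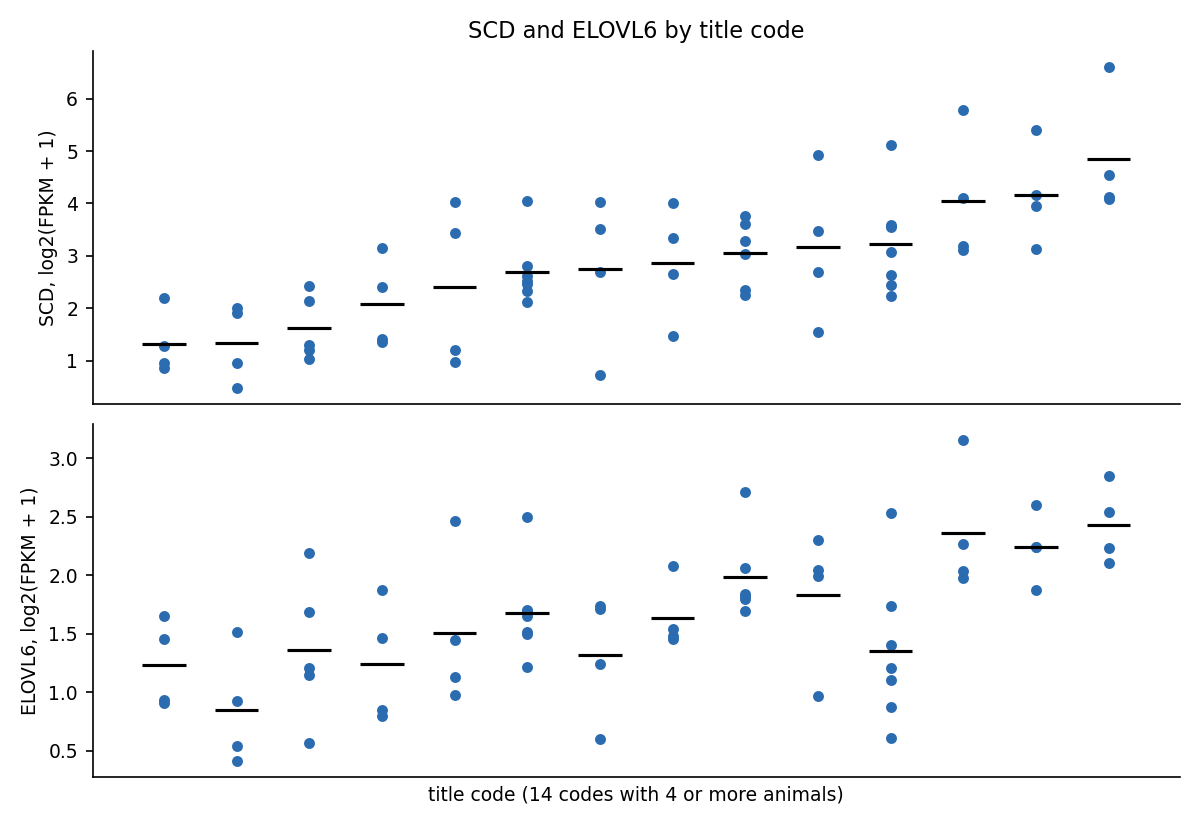
log2(FPKM + 1) of SCD (top) and ELOVL6 (bottom) per animal in the 14 title codes with at least 4 animals (65 animals), with codes in the same order of mean SCD in both panels. Points are animals and bars the code means, which range from 1.32 to 4.84 for SCD and from 0.85 to 2.43 for ELOVL6.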

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

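The screen for a library far from the others of its group was set before the data were examined. It was meant for groups of 4 to 10 libraries, and only the 10 re-analyzed libraries of high IMF are such a group. It covered 29 values there, and chance alone picks about 1 in 20 values. It picked 1, a number that chance alone can give. Among the 10 re-analyzed libraries of high IMF, ADIG, a gene of fat cell differentiation, was 2.40 log2(FPKM + 1) in library 148 and 1.40 in the next library, a gap of 0.473 of the whole range. Without library 148, 4 genes were higher at high IMF instead of 9, while leaving out other single re-analyzed libraries gave 0 to 17. No explanation was tested for it.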

How the results depend on the processing

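Chosen after seeing the data were the alternatives that tested transcripts, left out the 4 libraries least like the others, left out library 39 alone or within the first deposited libraries, or left out single libraries. Of the 9 genes rising with IMF, 9 were kept with a pseudocount of 0.1, no filter, the title code as a random block, IMF ranks or the first principal component. Under quantile normalization or with the first 4 digits of the title code 8 were kept. With no mark, under the median shift, without the 2 lowest and 2 highest IMF values or between the 41 animals highest and lowest in IMF 7 were kept. Except for the changes below, the cause of which was not tested unless given, the counts stayed within 1.5 times those reported.

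The number of genes rising with IMF was 19 with a pseudocount of 0.1, 18 with the first principal component as a covariate, and 30 without the 4 least-like libraries. It was 5 with a mean of at least 5 FPKM, where only 5 of the 9 were tested and all 5 were kept. In the first deposited libraries only it was 0 (limma; 270 at an unadjusted p under 0.05), and 5 there without library 39. Leaving out single libraries gave 6 to 28, with 28 without library 39. The number falling was 1 with no filter, 2 under quantile normalization (BEX1 and DDX20), 1 under the median shift and 1 with the first principal component (BEX1 in both). These genes were named after their values were seen.

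The number of lists past the threshold was 0 in the first deposited libraries only (r = 0.253 for adipocyte markers and 0.172 for fatty acid and triglyceride synthesis), and 1 there without library 39 (r = 0.334, adjusted p = 0.00168, for adipocyte markers, and r = 0.201 for fatty acid and triglyceride synthesis, adjusted p = 0.194).

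Between high and low IMF the number of higher genes was 5 with a pseudocount of 0.1, 5 with a mean of at least 5 FPKM and 2 for transcripts. Leaving out single libraries gave 0 (without low-IMF library 14 or 189) to 17 (without low-IMF library 104). The number lower was 1 under quantile normalization and 1 under the median shift (ELF2 in both, named after its value was seen), and 0 to 1 without single libraries (1 without high-IMF library 17).

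Between the sets, 1256 genes were higher and 997 lower with a mean of at least 5 FPKM, where fewer genes are tested. Of the genes called between the sets, the share that was higher was 44.6% as reported, 50.4% under quantile normalization, 54.3% under the median shift and 55.7% at 5 FPKM, so whether more genes are higher or lower depends on the scaling and the filter.

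For title codes the count was 109 under quantile normalization, 110 under the median shift, 45 with the first 6 digits as a factor, 35 for codes with at least 3 samples, 121 without the 4 least-like libraries and 112 for transcripts. Of the 195 genes, 85, 82, 36 and 31 were kept in the first 4 of these. With a pseudocount of 0.1, 9 of the 15 most variable genes stayed among the 15.

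Of the values of single genes and lists under the alternatives, 1496 slopes kept their sign and their side of the threshold. Another 25 fell short of the threshold, 8 newly passed it and 33, not called as reported, changed sign. Many are slopes of list members that were not called, and no change was compared with its error. No called value changed direction. Of the list correlations 294 kept their sign and their side of the threshold, 55, not called as reported, changed sign and 3 newly passed. Of the values of high against low IMF 27 were unchanged in this sense and 6 fell short, and of the ICC 87 and 8. Of the differences between the sets 70 were unchanged. Of the SDs 43 stayed within 1.5 times the reported value and 2 moved further. The alternative with Y-linked genes as a covariate was not run, since none of the 7 genes is in the table. Without read counts the precision at low expression is unknown, which bears on LEP, SNCG and SDR16C5.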

Other observations

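Chosen only after the result was seen were the tests of the difference between the sets, of library 39, of the fat-cell share, of fewer cells other than fibres, of transcript length over all lists apart between the sets, of the permuted title codes, of the first 6 digits for the gene count and of IMF within title codes, and the comparison of animals without IMF. The others were set beforehand.

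Scores of several related lists moved together over the 189 animals. How far the FPKM scaling contributes to these correlations was not tested. Genes of the fast fibre and glycolysis lists are among the most abundant ones, on which FPKM depend. Fast fibre genes followed glycolysis and glycogen (r = 0.713, adjusted p = 2.67e-05 over 8 pairs; rho = 0.655; 0.653 without the 2 farthest animals; 0.718 in the 168 libraries without the mark and 0.685 in the 21 with it). Adipocyte markers followed fatty acid and triglyceride synthesis (r = 0.770, rho = 0.729, 0.729 without the 2 farthest, 0.764 and 0.820 in the 2 sets) and collagen and fibroblast genes (r = 0.561, rho = 0.53, 0.527 without the 2 farthest, 0.577 and 0.427), both with an adjusted p of 2.67e-05. The underlying permutation p of these 3 pairs is 1e-05, the smallest they can give. Interferon response and macrophage and lymphocyte genes had r = 0.278 (adjusted p = 0.000128; rho = 0.192; 0.255 without the 2 farthest; 0.287 and 0.207), heat shock and immediate early genes r = 0.296 (adjusted p = 0.00012; rho = 0.289; 0.267; 0.263 and 0.578), and mitochondrial and nuclear oxidative phosphorylation r = 0.189 (adjusted p = 0.0121; rho = 0.183; 0.193; 0.149 and 0.673). Slow and fast fibre genes had r = -0.131 (adjusted p = 0.0859) and rho = -0.198 (adjusted p = 0.0110; -0.135 without the 2 farthest; -0.128 and -0.153). Circadian clock and immediate early genes had r = 0.0108 (p = 0.884) and rho = -0.0173.

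First deposited library 39 (IMF 3.05) held far more fat cell transcripts than the others. ADIPOQ was 604.7 FPKM in it (highest of the other 188, 75.3), FABP4 1676 (192), LEP 18.0 (2.67) and CIDEC 137 (34.9), whereas the fast myosin MYH4 was 288 FPKM (lowest of the others, 445). Its adipocyte score was 5.53 (next 1.81), its Schwann cell and nerve score 2.82 (next 1.88), its macrophage and lymphocyte score 2.20 (next 1.89), its collagen and fibroblast score 2.10 (next 1.43), its endothelial and pericyte score 2.06 (next 1.24) and its fast fibre score -2.37 (next -2.11). The 25 animals without a recorded IMF differed from the first deposited ones in 0 genes (limma; 360 at an unadjusted p under 0.05), and no list passed; the smallest p was that of circadian clock genes (score difference -0.26, p = 0.0138, adjusted p = 0.331).

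Adipocyte genes rise with IMF, with 9 genes called. Chance is argued against, since 1 of 100 permutations of IMF gave as many, the real one, and the highest other gave 1. The difference between the sets alone is argued against by r = 0.253 within the first deposited libraries (p = 0.00235), library 39 by 28 genes called without it, and a lower share of fibres by the adipocyte r exceeding the mean r of 4 other cell types by 0.349 (bootstrap range 0.226 to 0.495). What remains open is whether more fat cells or more transcript per fat cell is at work. Of the genes called without library 39 outside the list, 20 other than SFXN4 kept a median of 5.73% of their slope (-12.0 to 60.8) with the adipocyte score as a covariate, and 22.6% (-21.8 to 74.3) when library 39 was left out of that fit too. In the latter fit SDR16C5 kept 42.4% (adjusted p = 0.0828), SNCG 40.5% (0.0977) and PRDX5 74.3% (0.0898). The score takes up transcript per fat cell as well as fat cells, so these values do not part the 2. SFXN4 kept 86.6% (adjusted p = 0.0342), and 80.5% without library 39 (adjusted p = 0.0493), which argues against the fat-cell share as its whole cause, although its call with IMF is itself lost under both scalings. Within the first deposited libraries without library 39, 5 genes were called, 3 of them among the 9 and 1, LEP, on the adipocyte list, and 1 of 100 permutations gave as many (highest other 0).

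The re-analyzed libraries differ from the others in 4400 genes. A random choice of 21 libraries gave as many in 1 of 100 draws, the real one, and the highest other gave 181. For the collagen and fibroblast list, transcript length and exon number are argued against by its median of -0.52 (matched lists -0.165 to 0.111). They stay open for 4 of the 13 lists past the threshold, whose medians lie inside those of matched lists: cytosolic ribosomal (0.16, matched -0.03 to 0.22), nuclear oxidative phosphorylation (0.16, -0.04 to 0.20), myogenic and satellite cell (-0.18, -0.21 to 0.14) and pork quality genes (-0.16, -0.21 to 0.18). For animals at the extremes of IMF, the score of the called genes was set against the distance from the median IMF. In the first deposited libraries its slope was 0.115 (-0.154 to 0.385) where 1.15 would be needed. These genes were called between the same sets, which can raise the slope needed. First deposited IMF also ends at 5.61, against 6.84 in the re-analyzed libraries, so the test cannot decide. Fewer cells other than fibres may contribute, since all 7 scores of other cell types were lower, of which Schwann cell and nerve missed the threshold (adjusted p = 0.0538). The red blood cell score rests on 3 measured genes and the Schwann cell and nerve score on 4. A processing or library batch and the mark cannot be told apart, because no label gives them separately.

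Animals of the same title code resemble each other in 195 genes. Among 100 permutations of the codes, the real one included, 1 gave as many and the highest other gave 4. For the lipid synthesis score, a shared amount of fat cells alone is argued against by an ICC of 0.252 with the adipocyte score as a covariate (p = 0.0019). With the first 6 digits as a factor 45 genes were called, 36 of them among the 195, where 2 of 100 permutations gave as many and the highest other gave 73, and the lipid synthesis score had an ICC of 0.240 (p = 0.0659), so a shared origin of the 6 digits and the code itself cannot be told apart. IMF itself had an ICC of 0.182 (p = 0.0541, 122 animals of 42 codes), which leaves open whether it follows the code.

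Between the 10 re-analyzed libraries of high and the 11 of low IMF, 2 of 100 splits gave at least the 9 genes, the real split included. The highest other split gave 1091 genes, far more than the split by IMF. The cause of that count was not tested.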
